A study of Homo sapiens with 21 samples.

How the data were processed

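Total RNA from 7 populations of thymocytes, the developing T cells of the thymus, was hybridized to Illumina BeadChip expression arrays. The cells had been sorted from surgical human thymus tissue, and each population was profiled on 3 arrays, which gave 21 libraries. The groups are named here as the labels name them, by the surface proteins used for sorting. CD34+CD1a- and CD34+CD1a+ are progenitors, CD4ISP cells are immature CD4 single positives, and DPCD3- and DPCD3+ are double positives that carry CD4 and CD8. CD3+CD4+ and CD3+CD8+ are the mature single positives. The labels do not say whether a replicate number stands for a donor. Per the labels RNA was isolated in triplicate and 2 amplification kits were used, without saying which library had which. The spread between libraries of a group may therefore be partly technical, and the p-values measure the spread between these libraries.

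The deposited values are on a log2 scale. Their unit was read from the values, since the labels name no processing: they ran from 6.48 to 14.65, and the arrays had nearly the same distribution, each with a median of 7.33, as after quantile normalization. How the authors corrected background and which software they used is not given in the sources used here. The values are not centred on genes and still carry the background level, so fold changes of dim genes are understated. The plan fixed before the data were examined was to start from the raw intensities with a background correction based on detection p-values. The 21 columns of raw intensities carried no sample names that could be matched, and came without detection p-values. They were not matched to samples by their values. The raw intensities were therefore not used here, and the deposited log2 values took their place.

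The value table held 47226 probes, of which 30111 carried 1 gene symbol, 8 carried several and 17107 carried none. Probes with several symbols named no gene. A gene's position on the genome was not used. Background was estimated from the left flank of the distribution, with a mode of 7.22 and an SD of 0.21 (log2). The threshold at a tail probability of 0.01 was 7.71, and a probe was kept when it passed on at least 3 arrays, which 20028 did. Of 455 olfactory receptor probes, for genes that thymocytes are not known to express, more passed 7.71 than a probability of 0.01 allows. Their share per library ran from 2.2% in CD4ISP to 17.8% in DPCD3-. A level above 7.71 therefore does not by itself show expression. The probe with the highest mean stood for each gene. XIST and Y-linked genes were left out, and 10166 genes were tested. Signal over background limits the precision of arrays: 11074 to 11088 probes per array passed the threshold, a count that the normalization nearly fixes. Where all 3 arrays of the lower group were below background, a bound against the threshold is given as "at least". This bound is taken from group means and allows for the background only. It holds no sampling error, so a true change may be smaller than the bound, above all for genes that were not called.

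Models were fitted with limma 3.58.1 in R 4.3.3 to all 21 libraries, with 1 mean per group and 1 spread per gene (lmFit and eBayes). There were 7 comparisons of neighbouring or sister populations, an F test over all 7 populations, and the overlap of the changes of both mature groups against DPCD3+. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Throughout, "rose" and "fell" refer to called genes, fold changes are log2 with the standard error of the fit, and levels are mean log2 intensities with the SD of 3 arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

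Before the data were examined, 27 lists with 477 genes were fixed. Of these genes, 288 were measured, 38 were named by no probe and 151 lay below background. The lists were stem and progenitor regulators, T-lineage specification factors, Notch pathway targets, V(D)J recombination, T cell receptor complex and proximal signalling, DNA replication, mitosis, positive selection and TCR-induced genes, maturation and egress, CD4 lineage, CD8 and cytotoxic lineage, regulatory T cell, gamma-delta T cell, NK and innate-like cell, myeloid and conventional dendritic cell, plasmacytoid dendritic cell, B cell, erythroid cell, thymic epithelium and stroma, MHC class II, MHC class I and antigen processing, apoptosis regulators, interferon response, glycolysis, dissociation and stress response, T-ALL oncogenic transcription factors, and T-ALL tumour suppressors. Each was tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the 27 lists of a comparison, and again with a correlation estimated for each list. Members are counted as called over all genes and adjusted over the list alone. In 39 of the 189 list tests the median, the mean and the direction of the test differed in sign, and camera called 0 of these. fry served as an alternative; it tests whether a list's genes move 1 way, not against other genes.

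The rule for named genes was also fixed beforehand. It took the sort markers in every comparison, up to 6 called genes with the largest rise and 6 with the largest fall whose 3 values did not overlap those of the other group and were all above background in the higher group, and up to 4 called members of a list. Uncalled members are named with values only. For 3 against 3 libraries chance gives groups that do not overlap for 10% of genes. MLH3, the levels of CTLA4, CD8B, RUNX3 and EOMES in single libraries, the slopes of CTLA4 and ICOS, and the genes named in the last part of the closing section for a fit with the olfactory receptor share, were chosen after their values were seen.

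2 measures of signal were computed per library: the share of 455 olfactory receptor probes above the threshold, genes that thymocytes are not known to express, and the mean of 64 ribosomal protein genes, which are abundant in growing cells. Pairs of libraries within a group were compared over the tested genes. Replicate numbers were tested as pairs by correlating deviations from the group means: 11 of 21 libraries correlated best with a library of their own number in another group. No chance level was computed for this count, and deviations within a group are not independent. Same-number correlations were all above 0.1 only between CD3+CD4+ and DPCD3+ (0.52, 0.22 and 0.43), where a fixed replicate block called 3 genes in place of 4; a random block had a correlation of 0.0369.

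The method was tested on simulated data with the spread of these libraries: of 100 genes given a log2 change of 1, 53 to 63 were recovered per comparison, and of 100 given a change of 2, 96 or 97 were, with 5 to 9 false calls. Noise was drawn independently for each gene and library. Nearly identical libraries and differences in signal between libraries were not simulated, so these counts hold only for independent libraries. Alternatives fixed beforehand were another background correction (normexp with an offset of 50), no filter, a filter on all 3 arrays of a group, the mean of a gene's probes, only the 6 libraries compared, fixed and random replicate blocks, trend and robust variance, array weights, a 2-fold minimum, adjustment over all 7 comparisons, and leaving out each library. Added after the data were seen were both measures of signal as covariates, leaving out libraries that depart from their group (mean correlation with its mates under 0.95 and the lowest), averaging pairs of libraries that correlate at 0.98 or more, centring arrays on the median of the tested genes, and testing all probes.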

Results

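Expression was measured in 7 sorted populations of human thymocytes that span T cell development, with 3 libraries each, from CD34+CD1a- progenitors to CD3+CD4+ and CD3+CD8+ single positives. The stated purpose was to profile these populations, and each comparison below asks which genes differ between neighbouring stages or between the sister lineages. Values are deposited log2 intensities, and a level below 7.71 is not above background.

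The genes of the sort markers followed the sort in part. CD34, the surface marker of progenitors, was at 8.79 ± 0.99 (SD, n = 3) in CD34+CD1a- and 8.52 ± 0.43 in CD34+CD1a+, and below background on all arrays of the other 5 populations. In CD34+CD1a- replicate 2 it was also below background, at 7.65, against 9.32 and 9.4 in its group mates. CD1A, a lipid-presenting molecule of cortical thymocytes, was highest in CD4ISP, at 10.33 ± 0.33. It did not separate the progenitors that were sorted on this protein, with 8.86 ± 0.05 in CD34+CD1a- and 9 ± 0.57 in CD34+CD1a+. CD4 was below background on all arrays of both progenitor groups, at 8 ± 0.1 in CD4ISP and at 9.03 ± 0.11 in DPCD3-. CD8A did not separate CD4ISP from DPCD3-, with 8.06 ± 0.23 and 8.41 ± 0.91. The CD3 genes did not separate DPCD3- from DPCD3+. CD3D was at 9.26 ± 0.52 and 9.83 ± 0.95, CD3E at 8.73 ± 0.32 and 8.51 ± 0.88, and CD3G at 8.47 ± 0.4 and 8.65 ± 0.31. CD3D was as high in CD34+CD1a- (9.78 ± 0.32) and CD34+CD1a+ (10.33 ± 0.39) as in CD3+CD4+ (9.7 ± 0.39) and CD3+CD8+ (10.16 ± 0.3).

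In the mature populations the levels of CD4 and CD8A did not follow the labels. CD4 averaged 7.61 ± 0.97 in the libraries labelled CD3+CD4+ and 8.13 ± 0.52 in those labelled CD3+CD8+, and CD8A averaged 7.80 ± 0.57 and 8.06 ± 0.69. CD4 minus CD8A was 1.57, -1.1 and -1.05 in the 3 libraries labelled CD3+CD4+, and -1.2, 0.2 and 1.2 in the 3 labelled CD3+CD8+, so 2 libraries in each group had the other lineage's gene higher. The labels were kept as deposited. Every direction below that involves a mature group is a direction between libraries so labelled.

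**Figure D1:**
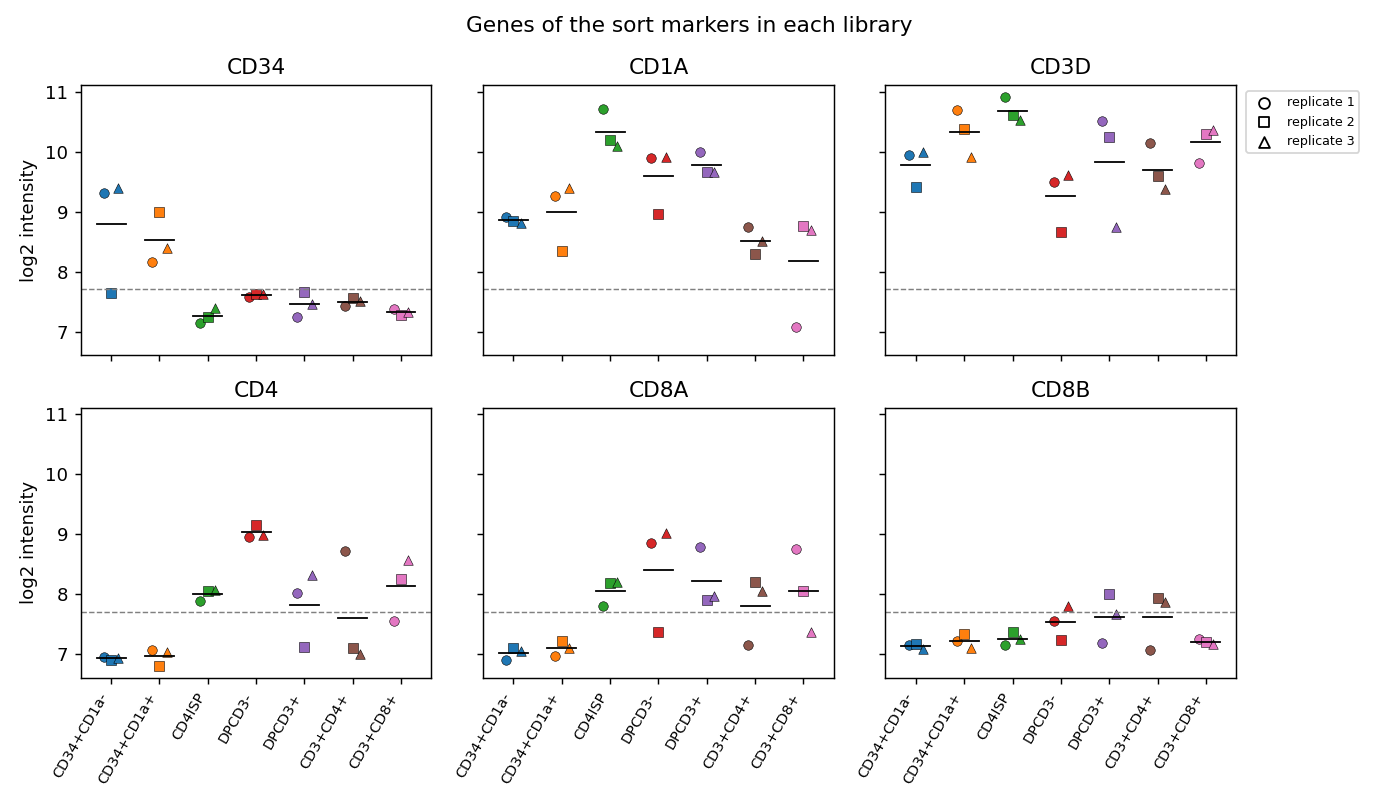
Level (log2 intensity) of 6 genes of the sort markers in the 21 libraries, by population; symbols are replicates, bars are group means, and the dashed line is the background threshold of 7.71. CD34 exceeds the threshold in 2 of 3 CD34+CD1a- and 3 of 3 CD34+CD1a+ libraries, and CD4 and CD8A are split within both mature groups.

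Libraries differed in how far transcripts stood out from the rest of the array. Olfactory receptor probes above background made up 2.34% ± 0.254 (SD, n = 3) of such probes in CD4ISP, 8.64% ± 4.13 in CD34+CD1a-, 9.45% ± 4.19 in CD3+CD8+, 11.1% ± 6.08 in CD34+CD1a+, 14.4% ± 4.26 in DPCD3+, 14.4% ± 3.41 in CD3+CD4+ and 15.2% ± 2.22 in DPCD3-. Ribosomal protein genes ran the other way, with a mean of 10.58 ± 0.06 in CD4ISP and 8.72 ± 0.46 in DPCD3-. Over the 21 libraries the ribosomal mean and the olfactory share had a Pearson r of -0.91 and a Spearman rho of -0.9, both with a permutation p of 1e-04, the smallest that 10000 permutations can give. Without the 2 libraries farthest in share r was -0.89. The first principal component of all tested genes held 54.1% of the variance and followed the olfactory share with r = 0.94 and rho = 0.95 (permutation p = 1e-04 each, 0.92 without the 2 farthest). These were the 2 relations computed, and adjustment over both leaves each p at 1e-04. The permutations moved all 21 libraries freely, although libraries of a population are alike and some are nearly identical. These p-values may therefore be too small. As deviations from group means the coefficients were -0.92 and 0.97.

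**Figure D2:**
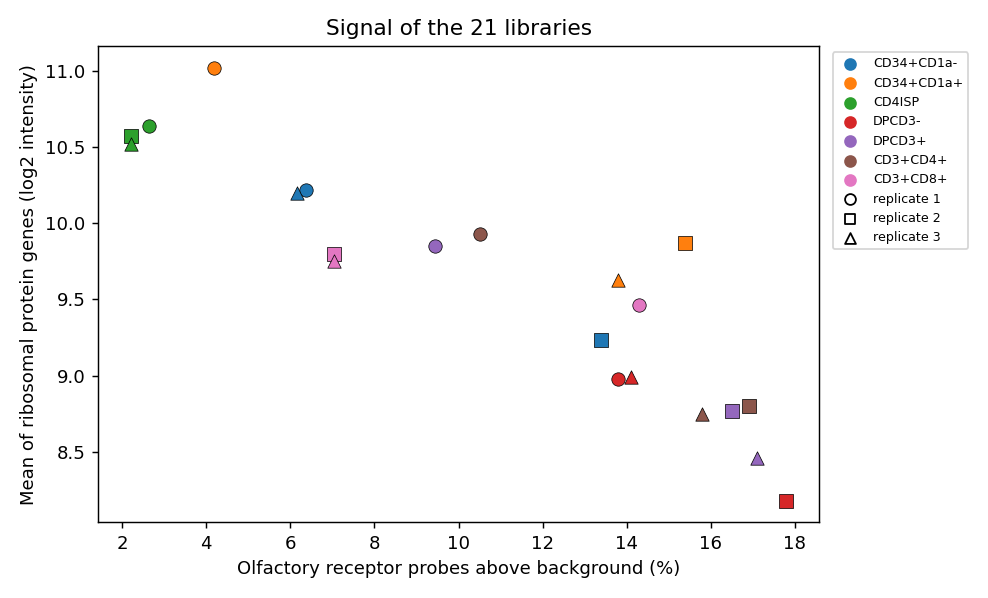
Mean of 64 ribosomal protein genes (log2 intensity) against the share of 455 olfactory receptor probes above background (%) in the 21 libraries; colours are populations and symbols replicates. The 3 CD4ISP libraries lie at 2.2% to 2.64%, and the DPCD3- libraries at 13.8% to 17.8%.

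In 5 groups, 2 of the 3 libraries were nearly identical. Their correlation over the tested genes was 0.983 to 0.994 and the SD of their difference 0.13 to 0.21 on the log2 scale, while the other 16 pairs within groups had correlations of 0.773 to 0.95 and SDs of 0.37 to 0.78. On background probes the close pairs differed with an SD of 0.14 to 0.18. The pairs were replicates 1 and 3 of CD34+CD1a- and DPCD3-, and replicates 2 and 3 of CD4ISP, CD3+CD4+ and CD3+CD8+. Counts with each pair averaged to 1 sample are given beside the main counts.

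Of the 10166 genes tested, 4631 (45.6%) varied among the 7 populations by limma's F test. Averaging close pairs left 35. With the olfactory share in the model it was 1679.

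**Figure D3:**
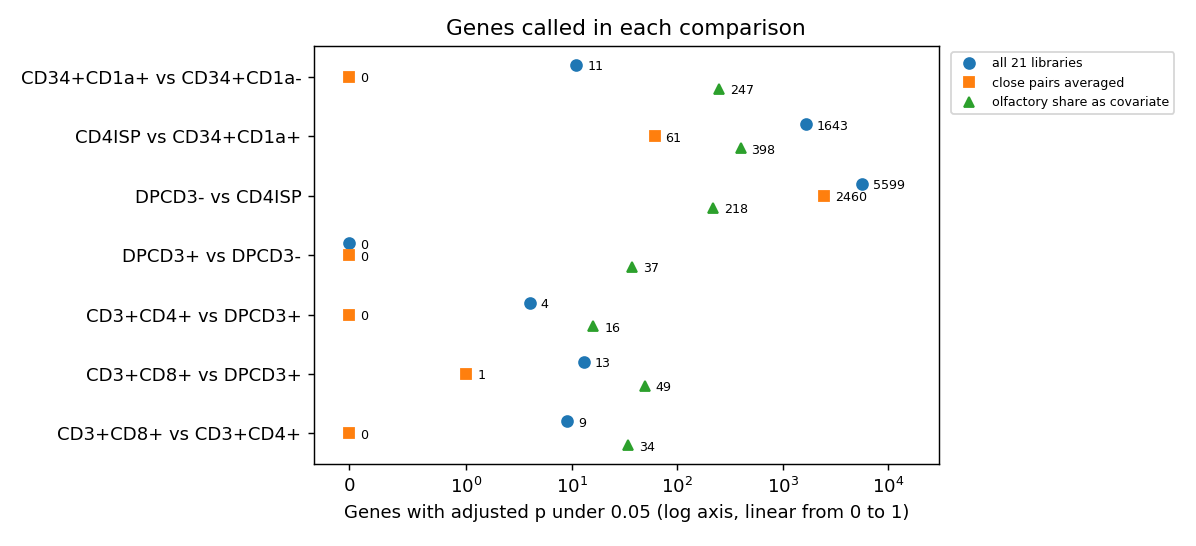
Genes with an adjusted p under 0.05 in each of the 7 comparisons (log axis, linear from 0 to 1) with all 21 libraries, with close pairs averaged, and with the olfactory receptor share as a covariate. DPCD3- against CD4ISP has 5599, 2460 and 218 genes, and DPCD3+ against DPCD3- has 0, 0 and 37.

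The step from CD34+CD1a- to CD34+CD1a+ progenitors asks what accompanies the gain of CD1a. PROM1, which encodes the stem cell antigen CD133, fell by 1.41 ± 0.19 (SE, n = 3), from 8.58 ± 0.03 (SD) to below background on all 3 arrays, at least 1.82-fold lower. The glycosyltransferase gene GCNT1 fell by 1.05 ± 0.18, PIAS2, which encodes a SUMO ligase, by 1.15 ± 0.21, and the zinc finger gene PRDM10 by 1.02 ± 0.16. The fifth gene that fell, the mismatch repair gene MLH3, was named after its value was seen; it fell by 1.07 ± 0.20. FZD9, which encodes a Wnt receptor of the Frizzled family, rose by 1.94 ± 0.32 from below background (at least 2.21-fold). PPP2R5B, a regulatory subunit of protein phosphatase 2A, rose by 1.79 ± 0.34, the Ras family gene RASD1 by 1.43 ± 0.26, and SLC25A11, which encodes a mitochondrial carrier, by 1.08 ± 0.19. DPY19L2P1 rose by 1.35 ± 0.26 and LINC01089 by 1.27 ± 0.23. The lower group was below background on all 3 arrays, which leaves only a bound, for RASD1 (at least 1.98-fold), DPY19L2P1 (at least 2.02-fold), LINC01089 (at least 1.85-fold), GCNT1 (at least 1.46-fold lower), PRDM10 (at least 1.28-fold lower) and MLH3 (at least 1.2-fold lower). These were the 6 genes that rose and 5 that fell in limma (adjusted p from 0.00455 to 0.0497); at unadjusted p under 0.05 there were 1082.

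No list was called between the progenitor groups in the main fit, with camera adjusted p of 0.0506 to 0.973 for the 27 lists. The lowest p belonged to the T-ALL tumour suppressors, genes lost or mutated in T cell leukaemia. Of 14 measured members 0 were called over all genes and 4 were lower adjusted over the list alone, among them the Polycomb genes EZH2 (-1.11 ± 0.38) and SUZ12 (-1.09 ± 0.35). Both fry and camera without a filter called this list lower in CD34+CD1a+. Camera without the libraries that depart from their group called DNA replication lower there. Of 10 stem and progenitor regulators PROM1 fell and LYL1 was higher by the list-alone adjustment (0.64 ± 0.20). Apoptosis regulators had 2 members higher and 2 lower adjusted over the list alone, with BCL2L1 at 0.74 ± 0.23 and MCL1 at -0.86 ± 0.32. HES4, a Notch target, was at 0.70 ± 0.21, VPREB1, the surrogate light chain gene of early B cells, at 1.10 ± 0.40, GIMAP8 at -1.11 ± 0.27 and the replication gene RFC5 at -0.75 ± 0.20 (at least 1.37-fold lower), none of them called over all genes. In limma 0 genes were called with close pairs averaged, and 0 from the 6 libraries alone. Without CD34+CD1a- replicate 2, the library without CD34 signal, 293 genes were called, and 117 without CD34+CD1a+ replicate 3. There were 18 without CD34+CD1a+ replicate 1, 2 without CD34+CD1a+ replicate 2, and 1 without CD34+CD1a- replicate 1 or replicate 3. PROM1 was the single named gene called in each of these fits. CD34+CD1a- replicate 2 also had an olfactory share of 13.4%, against 6.37% and 6.15% in its mates, which are a close pair. The fit without it leaves only that pair in its group, so the 293 genes cannot be read as progenitor differences alone.

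The step from CD34+CD1a+ progenitors to CD4ISP cells asks what changes as CD34 is lost and CD4 appears. RAG1, which encodes a subunit of the recombinase that assembles T cell receptor genes, rose by 2.07 ± 0.32 (SE, n = 3) to 10.88 ± 0.08 (SD). The T-lineage transcription factor gene ETS1 rose by 2 ± 0.34, TRAT1, which encodes an adaptor of the T cell receptor, by 1.26 ± 0.24, and CD1A by 1.33 ± 0.37. CD34 fell by 1.26 ± 0.32 to below background (at least 1.76-fold lower). The erythroid and megakaryocytic factor gene NFE2 fell by 1.94 ± 0.39, VPREB1 fell by 1.61 ± 0.40, the NK cell adhesion molecule gene NCAM1 fell by 1.46 ± 0.43 and the neutrophil protease gene CTSG fell by 1.17 ± 0.31. Against a lower group below background, NFE2 was at least 2.36-fold and CTSG at least 2.23-fold lower, and TRAT1 at least 1.73-fold higher. The proliferation marker MKI67 fell by 1.49 ± 0.32, while RFC4, a clamp loader subunit of DNA replication, rose by 1.61 ± 0.36. Over the populations MKI67 ran against the mitosis list. It was lowest in CD4ISP, at 7.61, where the list averaged highest (7.97). In CD3+CD4+ and CD3+CD8+ it was at 9.39 and 9.21, where the list was lowest (7.44 and 7.43). Its change is therefore not read as a change in proliferation. In all, 1643 genes were called, 1126 higher and 517 lower.

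The largest rises under the rule for named genes were in LUC7L3 (3.11 ± 0.56), PNISR (3.06 ± 0.61), PPIG (2.61 ± 0.56), the peptide transporter gene ABCB9 (2.46 ± 0.24, at least 4.51-fold), LRRC1 (2.42 ± 0.41) and ARPP21 (2.37 ± 0.38). The largest falls were in PPP2R5B (-2.56 ± 0.34, at least 4.63-fold lower), LOC105375297 (-2.08 ± 0.43), MIR1299 (-2.03 ± 0.38), the butyrophilin gene BTN1A1 (-2.03 ± 0.40, at least 2.67-fold lower) and the phosphodiesterase gene PDE3A (-1.97 ± 0.36). CD4 was at 1.03 ± 0.36 and CD8A at 0.96 ± 0.39 (at least 1.22-fold and 1.28-fold from below background), with adjusted p of 0.0592 and 0.0946 in limma.

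The V(D)J recombination list was higher in CD4ISP (camera adjusted p = 0.0289; adjusted p = 0.829 with an estimated correlation). Of 11 measured members 6 rose and 1 fell over all genes, and 8 and 1 adjusted over the list alone, with RAG1, HMGB1 (1.27 ± 0.35) and XRCC5 (1.15 ± 0.30), a Ku subunit of end joining, among those that rose. The call was lost with the olfactory share in the model, where the single list called was MHC class I and antigen processing, lower in CD4ISP. T cell receptor complex and proximal signalling had 5 of 17 members that rose and 0 that fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.0817). T-lineage specification factors had 3 of 14 that rose (5 over the list alone), T-ALL tumour suppressors 4 of 14, DNA replication 4 of 26, and mitosis 1 that rose and 2 that fell of 26. Lists of other cell types were not called by camera with all libraries: NK and innate-like cell genes had 1 of 5 that fell, myeloid and conventional dendritic cell 1 of 10, B cell 1 of 3, erythroid cell 0 of 3, and plasmacytoid dendritic cell 1 that rose and 1 that fell of 4. fry called the myeloid list lower, and camera without the libraries that depart from their group called the NK list lower. The 26 lists not called had camera adjusted p up to 0.99.

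The olfactory receptor share of CD4ISP differed from that of CD34+CD1a+ by -8.79 points (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 libraries allow), beside these rises. With close pairs averaged 61 genes were called, with the olfactory share in the model 398, 261 of them among the 1643, and without a single library from 516 (CD34+CD1a+ replicate 2) to 3409 (CD34+CD1a+ replicate 1), with 955 without CD34+CD1a+ replicate 3 and 525 and 602 without CD4ISP replicates 2 and 3. Of the 24 called genes named here, 16 were called without each library in turn, 3 with close pairs averaged, RAG1, ABCB9 and PPP2R5B, and 13 with the olfactory share in the model. Lost with the share were CD34, CD1A, TRAT1, MKI67, HMGB1, XRCC5, RFC4, NCAM1, PNISR, PPIG and LOC105375297. Of all 24, CD34, CD1A, HMGB1, XRCC5, RFC4, NCAM1, VPREB1 and CTSG each missed the threshold without CD34+CD1a+ replicate 2 or CD4ISP replicate 2, NCAM1 with -1.18 (limma adjusted p = 0.156) without the former.

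The step from CD4ISP to DPCD3- asks what changes at the double-positive stage, before the receptor reaches the surface. In all, 5599 of 10166 genes were called (55.1%), 2530 higher and 3069 lower, the highest count of the 7 comparisons; with the olfactory share in the model it was 218, below the 398 for CD4ISP against CD34+CD1a+. PTCRA, which encodes the pre-T cell receptor alpha chain, fell by 2.62 ± 0.36 (SE, n = 3), from 10.28 ± 0.36 (SD) to 7.65 ± 0.29. MYB, a transcription factor gene of early thymocytes, fell by 1.84 ± 0.25, DNTT, which encodes the terminal transferase that adds nucleotides to receptor junctions, by 2.31 ± 0.49, and HMGB1 fell by 2.32 ± 0.35. CD3D fell by 1.42 ± 0.37 and CD3G fell by 0.90 ± 0.28. CD4 rose by 1.03 ± 0.36. CD8A (0.35 ± 0.39) was not called, and CD8B was near background in both groups.

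The largest falls under the rule for named genes were in PNISR (-3.53 ± 0.61), the elongation factor gene EEF1B2 (-3.41 ± 0.67), the ribosomal protein genes RPS18 (-3.2 ± 0.64) and RPS24 (-3.09 ± 0.65), the mitochondrial import gene TOMM7 (-3.16 ± 0.58) and LZTFL1 (-3.13 ± 0.44, at least 7.06-fold lower). The largest rises were in the adaptor gene GRB7 (3.74 ± 1.07), the mucin gene MUC12 (2.94 ± 0.50), LOC105375297 (2.92 ± 0.43), the NK receptor gene KIR3DL1 (2.89 ± 0.37, at least 5.44-fold), UCA1 (2.88 ± 0.55) and SPMIP1 (2.87 ± 0.50). The olfactory receptor share was 12.9 points higher in DPCD3- (exact permutation p = 0.1, two-sided, the smallest possible), and the ribosomal protein mean was 8.72 ± 0.46 against 10.58 ± 0.06. In the DPCD3- libraries 13.8% to 17.8% of olfactory receptor probes passed the background threshold. For the genes that rose, a level above the threshold there does not by itself show expression.

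One list was called, dissociation and stress response, which was lower in DPCD3- (camera adjusted p = 0.0349; adjusted p = 0.682 with an estimated correlation): 9 of 14 members fell and 0 rose, among them the chaperone gene HSPA8 (-2.42 ± 0.62). With either measure of signal in the model, or without the libraries that depart from their group, it was not called. With the ribosomal mean in the model MHC class I and antigen processing was called higher in DPCD3- instead. DNA replication had 10 members that fell and 1 that rose of 26 (camera adjusted p = 0.0629), with RFC4 at -1.58 ± 0.36. V(D)J recombination had 6 that fell and 2 that rose of 11, T cell receptor complex and proximal signalling 6 and 0 of 17, T-lineage specification factors 7 and 2 of 14, Notch pathway targets 5 and 3 of 11, T-ALL tumour suppressors 6 and 1 of 14, and T-ALL oncogenic transcription factors 5 and 1 of 8. Mitosis had 7 that fell and 2 that rose of 26, and MKI67 rose by 1.65 ± 0.32, again against its list. Glycolysis had 9 and 5 of 18, with LDHB at -2.49 ± 0.65, and interferon response 7 and 4 of 19, with BST2 at -2.81 ± 0.51 (at least 5.67-fold lower). Apoptosis regulators had 4 that fell and 1 that rose of 13, maturation and egress 5 and 3 of 19, positive selection and TCR-induced genes 2 and 0 of 10, MHC class I and antigen processing 3 and 0 of 12, and MHC class II 2 and 0 of 4. Adjusted over the list alone the counts were the same, except that mitosis had 5 that fell, interferon response 8, and positive selection and MHC class I 0.

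Lists of other cell types were not called by camera, but fry called the NK, plasmacytoid dendritic cell, myeloid, and thymic epithelium and stroma lists higher. NK and innate-like cell genes had 4 of 5 members that rose and 0 that fell (camera adjusted p = 0.0659), NCAM1 by 2.43 ± 0.43. Plasmacytoid dendritic cell genes had 3 that rose and 1 that fell of 4, myeloid and conventional dendritic cell genes 2 and 1 of 10, thymic epithelium and stroma 2 and 1 of 5, B cell 1 and 1 of 3, CD8 and cytotoxic lineage 2 and 0 of 7, CD4 lineage 1 and 1 of 7, regulatory T cell 1 and 0 of 10, gamma-delta T cell 0 and 1 of 3, and erythroid cell 0 and 0 of 3. Stem and progenitor regulators had 3 that rose and 4 that fell of 10. The adjustment over the list alone gave the same counts. With the ribosomal mean in the model 278 genes were called. Of the 25 called genes named here 2, KIR3DL1 and MYB, were called with the olfactory share in the model, 22 with close pairs averaged and 23 without each library in turn. CD4 was not called without CD4ISP replicate 1 or DPCD3- replicate 2 (0.97 each), nor CD3G without DPCD3- replicate 1 (-0.76). With the olfactory share in the model GRB7 (-0.43), HSPA8 (0.24) and LDHB (0.13) turned direction, and none of these was called.

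The step from DPCD3- to DPCD3+ asks what accompanies the arrival of CD3 at the surface. No gene was called by limma, and 684 had an unadjusted p under 0.05. The positive selection and TCR-induced list was higher in DPCD3+ (camera adjusted p = 0.047; adjusted p = 0.699 with an estimated correlation). Of its 10 members 0 were called over all genes and 2 adjusted over the list alone. These were EGR1, an immediate early gene of receptor signalling (1.04 ± 0.22, SE, n = 3), and ITM2A, a gene induced in selection (2.06 ± 0.69, at least 3.53-fold). MHC class I and antigen processing was also higher (camera adjusted p = 0.03; adjusted p = 0.699 with an estimated correlation), with 0 of 12 members called by either adjustment. HLA-B was at 0.73 ± 0.32 (at least 1.11-fold) and B2M at 0.64 ± 0.54. The first list was called again only with close pairs averaged, and the second with close pairs averaged, with the olfactory share and with the replicate block. Averaging close pairs also called T-lineage specification factors and the T cell receptor list higher, and the plasmacytoid dendritic cell list lower. Without the libraries that depart from their group both calls were lost, and V(D)J recombination, DNA replication and mitosis were called lower in DPCD3+.

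Among members higher by the list-alone adjustment were the T-lineage factor gene TOX2 (2.03 ± 0.38), the adhesion gene CD44 (1.13 ± 0.39, at least 1.29-fold) and the chemokine gene CCL5 (0.65 ± 0.21). SPI1, which encodes the myeloid and early thymocyte factor PU.1, was at -1.74 ± 0.30 (at least 2.51-fold lower) and PROM1 at -1.13 ± 0.19 (at least 1.55-fold lower). Both had been higher in DPCD3- (9.04 ± 0.76 and 8.34 ± 0.13) than in CD4ISP (7.7 ± 0.08 and 7.11 ± 0.16). These lower values therefore do not continue a loss from the progenitors. TOX2, SPI1 and PROM1 each had an adjusted p of 0.0698 over all genes in limma. CD4 was at -1.21 ± 0.36 and CD3D at 0.57 ± 0.37. The other 25 lists had camera adjusted p of 0.0676 to 0.997. With the olfactory share in the model 37 genes were called, and with adjustment over all 7 comparisons 108. Without DPCD3- replicate 2 there were 27, and without DPCD3+ replicate 3 there were 40.

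CD3+CD4+ cells were compared with DPCD3+ to see what changes on the way to the CD4 lineage. RAG1 fell by 2.13 ± 0.32 (SE, n = 3), from 9.68 ± 0.30 (SD) to below background on all 3 arrays, at least 3.91-fold lower. KLF2, which encodes a factor that directs exit from the thymus, rose by 1.52 ± 0.23 to 9.04 ± 0.52. FCGBP, which encodes an IgG Fc-binding protein, rose by 1.34 ± 0.17 and the glycosyltransferase gene C1GALT1 by 1.18 ± 0.20, each from below background (at least 1.39-fold and 1.45-fold). These 4 genes, 3 higher and 1 lower, were all that limma called; 519 had an unadjusted p under 0.05. Deviations of the same replicate number correlate in this comparison, though replicate 1 also had the lowest olfactory share in both groups (10.5% and 9.45%). With the number as a block 3 genes were called, without C1GALT1 (1.18, limma adjusted p = 0.0793).

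The maturation and egress list was higher (camera adjusted p = 0.00146; adjusted p = 0.392 with an estimated correlation), with 1 of 19 members called by either adjustment, KLF2. The chemokine receptor gene CCR7 was at 0.82 ± 0.29, GIMAP7 at 0.51 ± 0.46 and the egress receptor gene S1PR1 at -0.08 ± 0.24. The V(D)J recombination list was lower (camera adjusted p = 0.00349; adjusted p = 0.392 with an estimated correlation), with RAG1 called over all genes and RAG1 and DNTT (-1.95 ± 0.49) adjusted over the list alone. Without the libraries that depart from their group neither list was called. IFI44 (0.96 ± 0.25) and PPP1R15A (0.67 ± 0.19) passed within their own lists. The lineage factor gene RUNX3 (0.25 ± 0.30) was not called, ZBTB7B was near background in both groups, and the other 25 lists had camera adjusted p of 0.0965 to 0.99. In limma 0 were called with close pairs averaged and 0 from the 6 libraries alone. Without DPCD3+ replicate 3 or CD3+CD4+ replicate 1 there were 23, and without DPCD3+ replicate 2 or CD3+CD4+ replicates 2 or 3 there were 2; FCGBP was called in each of these fits.

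CD3+CD8+ cells were compared with DPCD3+ for the CD8 lineage. RAG1 fell by 1.93 ± 0.32 (SE, n = 3) and the potassium channel gene KCNA4 by 1.33 ± 0.25. KLF2 rose by 1.78 ± 0.23 to 9.30 ± 0.31 (SD), and FCGBP by 2.04 ± 0.17, at least 2.25-fold. GMEB2, which encodes a DNA-binding protein, rose by 2.04 ± 0.36, RRAGB, a Rag GTPase gene of amino acid sensing, by 1.62 ± 0.28, MEIS3P1 by 1.60 ± 0.29 and CNNM2, which encodes a magnesium transporter, by 1.5 ± 0.28. These 4 were below background on all DPCD3+ arrays, so they rose at least 3.17-fold, 1.98-fold, 1.87-fold and 2-fold, and KCNA4, below background in CD3+CD8+, was at least 1.84-fold lower. In all, 11 genes rose and 2 fell in limma, and 944 had an unadjusted p under 0.05.

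The maturation and egress list was higher (camera adjusted p = 4.87e-09; adjusted p = 0.0944 with an estimated correlation). Of 19 members 1 was called over all genes and 8 adjusted over the list alone; these included GIMAP7 (1.46 ± 0.46), TXNIP (1.18 ± 0.37), S1PR1 (0.87 ± 0.24), CCR7 (0.76 ± 0.29), the interleukin-7 receptor gene IL7R (0.76 ± 0.21) and IL6ST (0.74 ± 0.25, at least 1.23-fold). Positive selection and TCR-induced genes were higher as a list (camera adjusted p = 0.000357; adjusted p = 0.311 with an estimated correlation) with 0 of 10 members called by either adjustment. Interferon response was higher too (camera adjusted p = 0.037; adjusted p = 0.316 with an estimated correlation), with 0 of 19 called over all genes and 2 over the list alone, IFI44 (1.29 ± 0.25) and MX1 (1.03 ± 0.29). With the olfactory share or the ribosomal mean in the model the positive selection and interferon lists were not called.

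DNA replication was lower as a list (camera adjusted p = 0.034; adjusted p = 0.701 with an estimated correlation), with 0 of 26 members called over all genes and MCM10 (-1.23 ± 0.30) adjusted over the list alone. V(D)J recombination had a camera adjusted p of 0.0503, with RAG1 called by either adjustment and DNTT at -1.32 ± 0.49. It was called lower with either measure of signal in the model, without a filter and with close pairs averaged, and with either measure of signal mitosis and Notch pathway targets were called lower too. Members that passed within their own lists included TRAT1 (1.23 ± 0.24, at least 1.82-fold), ICOS (1.33 ± 0.35) and HLA-B (1.12 ± 0.32) upward and CD1C (-1.08 ± 0.30) downward; 2 of 12 MHC class I members were higher, 1 of 7 CD4 lineage members was higher and 1 lower, and 2 of 3 erythroid cell and 1 of 3 B cell members were lower by this adjustment. fry called the erythroid cell and B cell lists lower. CD1A was at -1.61 ± 0.37. The olfactory share of CD3+CD8+ differed from that of DPCD3+ by -4.91 points (exact permutation p = 0.2, two-sided). Averaging close pairs left 1 called gene, FCGBP. Without CD3+CD8+ replicate 1 there were 172, without DPCD3+ replicate 1 or 3 there were 31 and 28, and without CD3+CD8+ replicate 2 or 3 there were 5 and 4; FCGBP and KLF2 were called in each fit that left out 1 library.

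**Figure D4:**
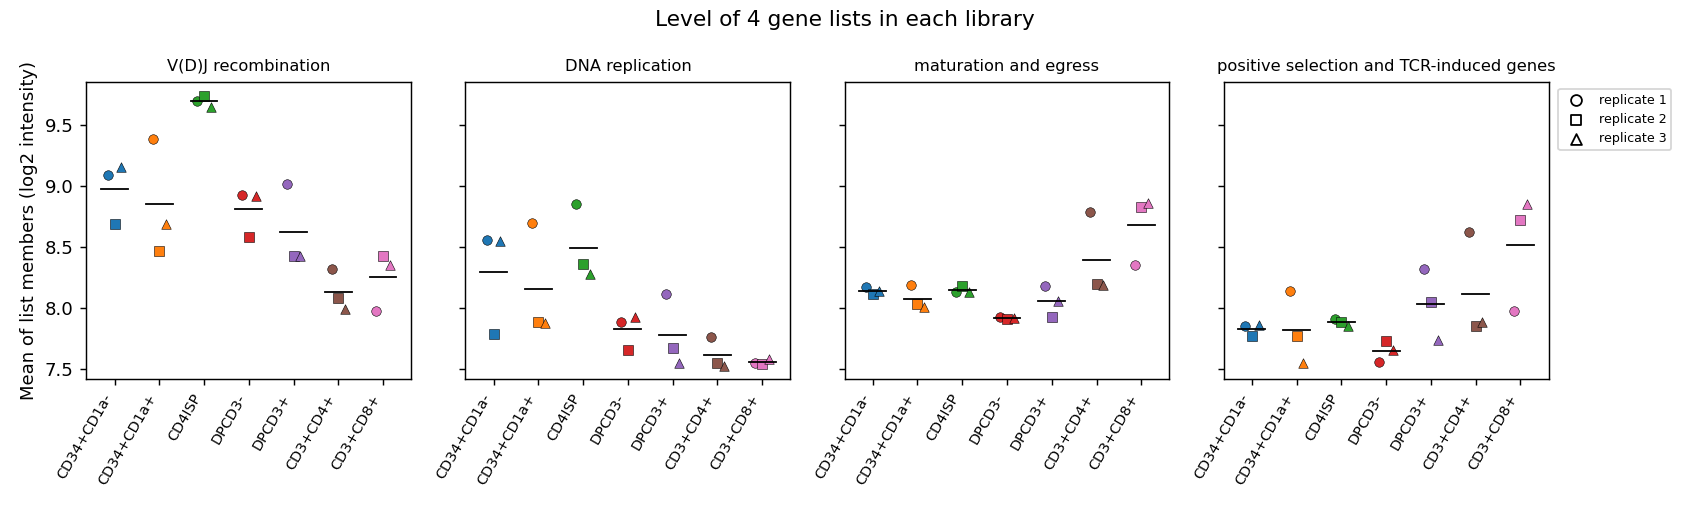
Mean of the measured members (log2 intensity) of 4 gene lists in the 21 libraries, by population; symbols are replicates and bars are group means. V(D)J recombination is highest in CD4ISP (9.69) and maturation and egress in the libraries labelled CD3+CD8+ (8.68).

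Both mature groups shared 3 changes against DPCD3+: KLF2 and FCGBP rose and RAG1 fell. Independent lists of these sizes would share 0.00325 higher and 0.000197 lower genes. Both contrasts use the same 3 DPCD3+ libraries, which are too few to be divided between them. Simulated data with no effect, in which the contrasts also share those libraries, gave a mean of 0 shared calls in 100 simulations and a correlation of fold changes across genes of 0.5, against 0.46 observed. Genes are not independent replicates, and this simulation drew each gene and library independently, without close pairs. The covariance of fold changes exceeded the simulated one by 0.00602 (0.0469 against 0.0408). With close pairs averaged 0 genes were shared, without DPCD3+ replicate 2 there was 1, and without DPCD3+ replicate 3 there were 11.

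The direct comparison of CD3+CD8+ with CD3+CD4+ asks what separates the lineages. In the libraries labelled CD3+CD8+, GOLM2, which encodes a Golgi membrane protein, was higher by 1.81 ± 0.30 (SE, n = 3), the neuronal factor gene NEUROD2 by 1.38 ± 0.19, the kinesin gene KIF1C by 1.25 ± 0.17, PSG4 by 1.16 ± 0.22 and SMN2 by 0.89 ± 0.17. FLT1, which encodes a VEGF receptor, fell by 1.74 ± 0.33, the glycosyltransferase gene MGAT1 by 1.22 ± 0.22, the ubiquitin ligase gene PELI1 by 1.10 ± 0.19 and KISS1 by 1.02 ± 0.18. Except for MGAT1 the lower group was below background on all 3 arrays, which leaves bounds of at least 2.47-fold for GOLM2, 2.17-fold for NEUROD2, 1.52-fold for KIF1C, 1.67-fold for PSG4, 1.47-fold for SMN2, 2.24-fold for FLT1, 1.34-fold for PELI1 and 1.86-fold for KISS1. These 5 higher and 4 lower genes were all that limma called, and 871 had an unadjusted p under 0.05. None is a lineage gene of the fixed lists. CD4 (0.52 ± 0.36), CD8A (0.26 ± 0.39), RUNX3 (-0.45 ± 0.30) and EOMES (-0.33 ± 0.20) were not called, and CD8B and ZBTB7B averaged below or near background in both groups.

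As lists, positive selection and TCR-induced genes and maturation and egress were higher in CD3+CD8+ (camera adjusted p = 0.00941 each; adjusted p = 0.489 each with an estimated correlation). Over all genes 0 members of either were called. Adjusted over the list alone 1 of 10 was called in the first, EGR1 (1.02 ± 0.22), and 1 of 19 in the second, S1PR1 (0.95 ± 0.24); TRAT1 (0.97 ± 0.24) passed within its list. In each group 1 library stood apart. Positive selection members averaged 8.62 in CD3+CD4+ replicate 1 against 7.85 and 7.89 in its mates, and 7.98 in CD3+CD8+ replicate 1 against 8.72 and 8.85; for maturation the values were 8.79 against 8.2 and 8.19, and 8.35 against 8.83 and 8.86. Replicate 1 of each group thus lay nearer replicates 2 and 3 of the other. With the olfactory share or the ribosomal mean in the model, or with close pairs averaged, neither list was called. The CD4 lineage list had a camera adjusted p of 0.449 and the CD8 and cytotoxic lineage list 0.899, and the 25 lists not called ran from 0.0699 to 0.943. The olfactory share of CD3+CD8+ differed from that of CD3+CD4+ by -4.98 points (exact permutation p = 0.2, two-sided). With close pairs averaged 0 genes were called, and with arrays centred on the median of the tested genes 4, 3 higher and 1 lower (75% against 55.6% higher). Without CD3+CD4+ replicate 1 or CD3+CD8+ replicate 1 there were 54 and 60 genes, without CD3+CD4+ replicate 3 or CD3+CD8+ replicate 3 there were 3 and 2, and without replicate 2 of either group 0, so none of the 9 was called in each of these fits.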

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

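All tests in this part were chosen after the results were seen. The items weighed are the 9 genes that differed between the libraries labelled CD3+CD8+ and CD3+CD4+. KIF1C (1.25), NEUROD2 (1.38) and GOLM2 (1.81) were higher in CD3+CD8+, and against DPCD3+ they stood at 1.37, 1.49 and 1.18 in CD3+CD8+ and at 0.12, 0.11 and -0.63 in CD3+CD4+. SMN2 (0.89) stood at 0.62 and -0.27 against DPCD3+. PSG4 (1.16) stood at -0.01 and -1.18, so its difference lay in the libraries labelled CD3+CD4+. FLT1 (-1.74), MGAT1 (-1.22), PELI1 (-1.1) and KISS1 (-1.02) were higher in CD3+CD4+. Against DPCD3+ they stood at 1.14, 0.27, 0.75 and 0.49 in CD3+CD4+ and at -0.61, -0.96, -0.35 and -0.54 in CD3+CD8+, so the difference in MGAT1 lay mainly in CD3+CD8+. For all but MGAT1 the lower group was below background, so these differences are not exact.

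No tested gene of the fixed lineage lists was among the 9, and the levels of CD4 and CD8A were against the label in 2 of 3 libraries of each group. Of the 10 splits of these 6 libraries into 3 and 3, 2 called at least as many genes as the real split, with 201 at most in another split against 9. The splits are too few for a share under 0.05. The split with 201 sets CD3+CD4+ replicate 1 with CD3+CD8+ replicates 2 and 3 and also parts the libraries by olfactory receptor share, so it points to a structure of the samples other than the labels. For the gene lists 4 of the 10 splits called at least as many as the real split, with 5 at most against 2. The 9 genes may therefore reflect differences between single libraries as well as between lineages, and without CD3+CD4+ replicate 2 or CD3+CD8+ replicate 2 limma called 0 genes.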

How the results depend on the processing

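Alternatives fixed before the data were examined come first. The tests with covariates, without departing libraries, with close pairs averaged, with centred arrays and with all probes were chosen after the results were seen. Comparisons are given in the order of development: CD34+CD1a+ against CD34+CD1a- (11 genes), CD4ISP against CD34+CD1a+ (1643), DPCD3- against CD4ISP (5599), DPCD3+ against DPCD3- (0, with 684 at unadjusted p under 0.05), CD3+CD4+ (4) and CD3+CD8+ (13) against DPCD3+, and CD3+CD8+ against CD3+CD4+ (9). Only values that moved by more than 1.5 times or lost a call are listed. Where no cause is given, the cause was not tested.

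Another background correction and a filter on all 3 arrays moved no count by more than 1.5 times, nor did the mean of probes. The background correction was applied to the deposited values, whose distributions were already nearly the same. It changed every array in nearly the same way, so it says little about how the results depend on background correction. Fitting without a filter gave 32 genes for the progenitors and 17 between the mature groups. Only the 6 libraries compared gave 0, 579, 0 (CD3+CD4+), 1 (CD3+CD8+) and 0 genes for the first, second and last 3 comparisons, and 0 shared changes. Trend and robust variance gave 41 genes for the progenitors and 2 between the double positives. The 2-fold minimum left 754 and 2882 genes for CD4ISP and DPCD3-. With adjustment over all 7 comparisons together the counts were 218 for the progenitors, 3670 for DPCD3- against CD4ISP, 108 between the double positives, 80 and 156 for the mature groups against DPCD3+, 145 between them, and 20 shared; the many small p-values of DPCD3- against CD4ISP set a looser threshold for the others.

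Array weights gave 1295, 4277, 8588, 223, 117, 1551 and 5977 genes for the 7 comparisons, 9952 varying among populations and 47 shared. CD3+CD8+ replicate 2 took a weight of 117.36 in that fit, with 7.43 as the next highest, and the estimate did not fully converge.

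A fixed replicate block gave 7 genes for the progenitors, 2 between the double positives and 4 between the mature groups, and lists went from 1 to 2 for DPCD3- against CD4ISP and from 2 to 1 for DPCD3+ against DPCD3-. A random block moved no count by more than 1.5 times. Same-number correlations were all above 0.1 only for CD3+CD4+ against DPCD3+, where the block called 3 genes in place of 4, without C1GALT1, and the same 2 lists. The labels show no pairing in any comparison, and 11 of 21 libraries correlated best with one of their own number, a count without a computed chance level.

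The olfactory receptor share as a covariate gave 247, 398, 218, 37, 16, 49 and 34 genes, 1679 varying and 5 shared. With the ribosomal protein mean instead there were 188 genes for the progenitors, 278 for DPCD3- against CD4ISP, 28, 10, 56 and 19 for the last 4 comparisons, 1765 varying and 5 shared. The share varied within most groups and did not overlap between CD4ISP and DPCD3-, where the count fell most.

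Leaving out libraries that depart from their group gave 2890 genes for the progenitors, 5248 for CD4ISP, 700, 451, 2251 and 2539 for the last 4 comparisons, 7748 varying and 191 shared. This setting keeps mostly close pairs, whose spread is small. With close pairs averaged the counts were 0, 61, 2460, 0, 0 (CD3+CD4+), 1 (CD3+CD8+) and 0 between the mature groups, with 35 varying and 0 shared. All probes above background gave 22, 3026 and 10901 for the first 3 comparisons, 14 between the mature groups and 8588 varying. Arrays centred on the median of the tested genes gave 4 between the mature groups, and shifted the median log2 change by at most 0.08 in size.

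Without 1 library at a time the counts ran from 1 (without CD34+CD1a- replicate 1 or 3) to 293 (without CD34+CD1a- replicate 2) for the progenitors, from 516 (CD34+CD1a+ replicate 2) to 3409 (CD34+CD1a+ replicate 1) for CD4ISP, from 4449 to 4876 for DPCD3- against CD4ISP, and from 0 to 40 (DPCD3+ replicate 3) for DPCD3+ against DPCD3-. For CD3+CD4+ against DPCD3+ they ran from 2 to 23, for CD3+CD8+ from 4 (CD3+CD8+ replicate 3) to 172 (CD3+CD8+ replicate 1), and between the mature groups from 0 (replicate 2 of either) to 60 (CD3+CD8+ replicate 1). Genes varying ran from 2669 (CD4ISP replicate 2) to 5429 (CD34+CD1a- replicate 2), and shared changes from 1 (DPCD3+ replicate 2) to 11 (DPCD3+ replicate 3).

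With an estimated correlation 0 lists were called in each comparison. fry called 1 list for the progenitors, 4 for CD4ISP, 17 for DPCD3- against CD4ISP, 0 between the double positives, 0 for CD3+CD4+ against DPCD3+ and 0 between the mature groups. Without a filter there were 1, 3, 2 and 0 lists for the first 4 comparisons. With the olfactory share 0 lists were called for DPCD3- against CD4ISP, 1 for DPCD3+ against DPCD3- and 1 between the mature groups. The ribosomal mean as a covariate gave 0 for DPCD3+ against DPCD3-, 4 for CD3+CD4+ against DPCD3+ and 1 between the mature groups; the list called there with either covariate was DNA replication, lower in CD3+CD8+. Without departing libraries there were 1, 3 and 0 lists for the first 3 comparisons, 0 for CD3+CD4+ against DPCD3+ and 5 between the mature groups. Close pairs averaged gave 2 for DPCD3- against CD4ISP, 5 for DPCD3+ against DPCD3- and 0 between the mature groups. Maturation and egress stayed called in CD3+CD8+ against DPCD3+ with fry, with either covariate, with the fixed block, without a filter, without departing libraries and with close pairs averaged; with the estimated correlation it did not. Other calls were lost more often, even where a count did not move. In the same comparison positive selection was lost with fry and either covariate, interferon response with these and without departing libraries, and DNA replication with fry, without a filter and without departing libraries. V(D)J recombination was lost in CD4ISP with the olfactory share, where MHC class I was called lower, and the stress list in DPCD3- with either covariate and without departing libraries. MHC class I was called higher in DPCD3- with the ribosomal mean. Between the double positives positive selection was lost with fry, the fixed block, no filter, either covariate and without departing libraries, and MHC class I with fry, no filter, the ribosomal mean and without departing libraries. Without departing libraries V(D)J recombination, DNA replication and mitosis were called lower there instead. V(D)J recombination was gained, lower in CD3+CD8+ than in DPCD3+, with either covariate, without a filter and with close pairs averaged, and mitosis and Notch pathway targets with either covariate. Between the mature groups both lists were lost with fry, either covariate and close pairs averaged.

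For single genes, 3907 alternative values were computed for 178 named values: 3416 were the same, 293 weaker, 193 stronger and 5 reversed. The 5 were all in DPCD3- against CD4ISP: GRB7 at -0.43 with the olfactory share and -0.68 with the ribosomal mean, HSPA8 at 0.24 with the olfactory share, and LDHB at 0.13 and 0.17, none of them called. Quantile normalization had made the arrays alike, so median scaling was void, as were the deposited values and no background correction, which equal the values used; a slide block was not run because the labels give no slide.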

Other observations

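All tests in this part were chosen after the results were seen. Among all 21 libraries 4631 genes varied, and of 100 drawn splits into 7 groups of 3, 1 gave as many, the real one, with 1404 at most in the others. These splits break up the nearly identical pairs that the real groups hold, so they do not measure chance among separate samples. Of 100 splits that keep each close pair in 1 group, 6 gave as many genes, the real one included, with 5877 at most in the others. In these splits each pair still stands in a group apart from the other pairs, so differences between their populations remain. They give no reference without an effect, and chance is neither shown nor excluded. The 3 shared changes of both mature groups were matched by 4 of 100 splits of the 9 libraries (3 real, 3 highest other), a share under 0.05. Those splits too break up close pairs. Of the 60 splits that keep the close pairs together, 24 shared as many genes, with 60 at most in the others. There the pairs of CD3+CD4+ and CD3+CD8+ stay in separate groups, so the same limit holds and chance is neither shown nor excluded.

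For each single comparison the 10 splits are too few for a share under 0.05. Counting the real split, 2 splits called at least as many genes for the progenitors (11 real, 1775 highest other), 1 for CD4ISP (1643, 217), 1 for DPCD3- against CD4ISP (5599, 0), 10 for DPCD3+ against DPCD3- (0, 60), 3 for CD3+CD4+ (4, 50) and 3 for CD3+CD8+ (13, 144). For lists the counts of splits were 10 (0, 2), 7 (1, 3), 5 (1, 5), 4 (2, 4), 4 (2, 4) and 2 (4, 5). The progenitor split with 1775 genes sets CD34+CD1a- replicates 1 and 3 with CD34+CD1a+ replicate 1. The split with 60 genes sets DPCD3- replicates 1 and 3 with DPCD3+ replicate 1, the split with 50 sets DPCD3+ replicates 1 and 2 with CD3+CD4+ replicate 1, and the split with 144 sets DPCD3+ replicate 1 with CD3+CD8+ replicates 2 and 3. Each points to a structure of the samples other than the labels, and all but the split with 50 part the libraries by olfactory receptor share without overlap. For CD3+CD4+ against DPCD3+, where deviations of the same number correlate, 4 splits part all 3 number pairs as the real one does. The highest of the other 3 gave 0 genes, and the split with 50 keeps a number pair together. Replicate 1 had the lowest olfactory share in both groups (10.5% and 9.45%), so signal and a true pairing cannot be told apart there.

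The 5599 genes that changed from CD4ISP to DPCD3- may largely reflect weaker specific signal in the DPCD3- libraries. Across genes their log2 change had a correlation of 0.83 with the slope on the olfactory receptor share inside the other 5 groups, and 93.7% of the called genes had the slope's sign. With the share as a covariate the median size of the change of these genes went from 1.02 (median SE 0.26) to 0.4 (0.31), so most calls ended through a smaller change and not through a wider error. A difference between the populations stays open: 198 genes were called with and without the covariate, 67 higher and 131 lower, among them ABCB9 (-2.7), KCNG1 (2.66) and ARHGAP33 (-2.23), but the shares of the groups do not overlap, which keeps the rest undecided. Whether the lower signal comes from the RNA, its amplification or the cells was not tested.

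The 1643 genes that changed from CD34+CD1a+ to CD4ISP may in part reflect stronger specific signal in the CD4ISP libraries. Their log2 change had a correlation of -0.58 across genes with the slope on the olfactory receptor share inside the other 5 groups, and 86.3% of the called genes had the sign opposite to the slope, as the lower share of CD4ISP predicts. With the share as a covariate the median size of their change went from 0.96 (median SE 0.24) to 0.6 (0.25). A difference between the populations stays open: 261 genes were called with and without the covariate, 219 higher and 42 lower, but the shares do not overlap (2.64% at most in CD4ISP, 4.18% at least in CD34+CD1a+), which keeps the rest undecided.

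In 5 groups 2 of the 3 libraries were nearly alike, and differences in specific signal alone are unlikely to explain it. Once each gene's slope on the olfactory receptor share was removed, the other pairs still differed 2.44 times as much as the close pairs. In the close pairs the spread of differences over tested genes was 1.12 times that over background probes, so repeated arrays of 1 RNA may account for some pairs, while the labels, which speak of RNA isolated in triplicate, leave separate isolations from the same cells open. The tests of the report treat all libraries as replicates, and their p-values are too small if these are repeats.

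In the mature libraries, labels exchanged between the groups are a candidate explanation for CD4 and CD8A levels against the label in 2 of 3 libraries of each group. CD4 minus CD8A followed the mean of the CD4 lineage list minus that of the CD8 and cytotoxic list with r = 0.91 (exact permutation p = 0.0264) and rho = 0.94 (exact permutation p = 0.0167). Without the 2 farthest libraries r was 0.97. Replicates 2 and 3 of each mature group are close pairs. These p-values, and the SEs of slopes in the 6 mature libraries, are too small if the pairs are repeats. CTLA4 (9.07, 7.42 and 7.33 in CD3+CD4+, and 7.15, 9.24 and 9.39 in CD3+CD8+) had the same split. CTLA4 and ICOS are members of the CD4 lineage list, and RUNX3 and EOMES of the CD8 and cytotoxic list. Their splits are thus parts of that correlation and not separate support. Of the CD8 genes, RUNX3 (7.86, 9.24 and 9.39, and 8.63, 8.61 and 7.9) went partly that way, and EOMES (7.87, 8.32 and 8.43, and 8.11, 7.86 and 7.64) did so in all 6 libraries. But their slopes on the olfactory receptor share inside the earlier groups ran in the same direction as in the mature libraries (0.022 ± 0.014 against 0.112 ± 0.048, and 0.028 ± 0.015 against 0.064 ± 0.012), so signal may account for part of it. CD8B went that way in CD3+CD4+ (7.08, 7.94 and 7.87) and was below background in all 3 libraries labelled CD3+CD8+ (7.25, 7.21 and 7.17). An exchange would leave CD8B low in replicates 2 and 3 of CD3+CD8+ but not in replicate 1, so only the 7.25 goes against it. CD4 against CD8A alone had r = -0.72 (exact permutation p = 0.119) and rho = -0.6 (exact permutation p = 0.242); these were the 2 relations computed, and the lists share the biology of the 2 genes. Weaker signal in some libraries stays open: the slope of CD4 minus CD8A on the olfactory receptor share was 0.026 ± 0.046 (SE) log2 per point inside the 5 earlier groups and -0.225 ± 0.087 in the 6 mature libraries, the list score had 0.01 ± 0.01 and -0.071 ± 0.019, and CTLA4 0.001 ± 0.02 and -0.229 ± 0.042, but CD4 and CTLA4 lie near background in several earlier groups. ICOS also splits this way, but its slope inside the earlier groups was -0.099 ± 0.015 against -0.126 ± 0.014. The olfactory receptor share parts the mature libraries the same way, so the split of ICOS cannot tell signal from an exchange. The labels were kept, and no result here rests on an exchange.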
